A study of Mus musculus with 9 samples.

How the data were processed

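RNA was measured in cells of embryonic mouse heart ventricles that were grown in culture and sorted at harvest for a cardiomyocyte marker. Ventricles of CD-1 mouse embryos (an outbred strain) at embryonic day 13.5 were pooled by litter and digested with papain, and the cells that did not attach quickly to plastic were kept, per the labels' protocols. Per the same protocols, the cells grew for 48 h and were then transfected by lipofection with 0.012 pmol of siRNA, short double-stranded RNA that directs the cleavage of a matching transcript. The siRNA was a pool of 4 against Dnmt3a, a pool of 4 against Dnmt3b, or a commercial negative control. Cells were harvested 72 h later and sorted on magnetic columns with an antibody to VCAM1, a surface protein used to mark embryonic cardiomyocytes, per the labels' protocols. Poly(A) RNA was made into libraries with a kit that the protocols do not describe as keeping strand, and sequenced on an Illumina NextSeq500. The labels give 3 groups of 3 libraries and number the libraries 1 to 3 within each group. They do not say whether libraries of a group came from separate litters or cultures, so p-values measure only the spread between these samples, which may be technical.

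The authors deposited 1 table of read counts per library, with whole-number counts for 43629 Ensembl mouse genes and 5 summary lines. The submitters' processing notes name FastQC, TopHat2 (a spliced read aligner), HTSeq (a read counter) and the mm10/GRCm38 genome build, without versions or roles. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited counts were not normalised. Reads that matched several places, no annotated feature or more than 1 gene stood in the summary lines, which held 49.2% to 56.2% of each table's total and were left out of library sizes and tests. Of each total, 36.6% to 42.5% were alignments that were not unique, 8.40% to 11.9% lay in no annotated feature, and 1.92% to 2.45% were ambiguous. The share that was not unique separated the groups: 36.6% to 40.1% after DNMT3a siRNA, 41.3% to 42.5% in controls and 41.5% to 42.5% after DNMT3b siRNA. This difference in the reads cannot be told apart from an effect of DNMT3a siRNA. Reads that were not unique were not counted in any gene. Genes with near-identical copies are therefore undercounted: Gapdh, which has many pseudogenes, is uncertain for this reason. Without a known strand setting, overlapping and antisense genes such as Kcnq1 and Kcnq1ot1 are uncertain too. All mitochondrially encoded genes had a count of 0 in the 9 libraries, so none was analysed here.

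Gene symbols, coordinates and gene lengths came from GENCODE mouse release 21 (GRCm38), in which 42548 of the gene identifiers had a symbol and 1081 had none. Libraries are called control 1 to 3, DNMT3a 1 to 3 and DNMT3b 1 to 3 after their group and number. Reads counted in genes ran from 27852412 to 35896018 per library with a median of 31102332. Genes with 0 counts in every library numbered 11444. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 16561, and libraries were scaled by the TMM method. All 9 libraries entered 1 quasi-likelihood fit with group as the only term and 6 residual degrees of freedom (edgeR 4.0.16, R 4.3.3, robust fitting, biological coefficient of variation 0.154). Each pair of groups was compared by the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the 16561 genes, and an adjusted p under 0.05 was called a change. Every adjusted p given for a gene comes from this test unless another is named. A log2 fold change is followed by its standard error, computed from the fold change and its F statistic. Expression levels are TMM-scaled CPM, counts brought to a common library total,, as the mean and standard deviation over 3 libraries. The design, the alternatives, the rule for naming genes and 29 gene lists with 758 genes were fixed before the data were examined.

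Gene lists were compared with all other genes by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 26 lists. The 3 lists with fewer than 3 measured members were not tested: erythroid genes (1 of 17 measured), mitochondrially encoded genes (0 of 15) and the sort marker Vcam1 alone. Camera with a correlation estimated per list and the rotation test fry were run beside it. Some genes stood in more than 1 list, for example Tcf21 in the fibroblast and epicardial lists, Xirp1 in the sarcomere and load-response lists, and Sdha in the respiratory-chain and housekeeping lists. List members were also counted with the p-value adjusted over the list alone.

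Genes were named by rule. Dnmt3a, Dnmt3b, Dnmt1, Vcam1, Myh6, Myh7, Tnnt2, Tnni3, Nppa, Nkx2-5 and Gata4 were named in each comparison whatever their values. The 8 largest rises and 8 largest falls were taken among changed protein-coding genes with an average log2 CPM of at least 2 and all 3 libraries of a group on the same side of the 3 others, and 5 each way for the knockdowns against each other. Up to 4 changed members of each list with the smallest adjusted p were added. Any other gene named was chosen after its values were seen. A few genes are not reported here by name, although they stay in the tests and counts.

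Whether library numbers pair samples was checked from the data, since the labels do not say what a number marks. Deviations from the group means correlated across genes between control and DNMT3a libraries of the same number with r = 0.434, 0.513 and 0.459. As each exceeded 0.1, these comparisons are read as paired, and the fit with the number as a block is given beside a result where it changes a call or moves a count by over 1.5 times. No replicate pair agreed within sampling noise: chi-square per degree of freedom ran from 6.42 to 59.7 over genes with a count of at least 20, so each library counted once.

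The tests were tried on simulated counts drawn with the real means, dispersions and library sizes. For the DNMT3a comparison, over 16341 genes, 65% of 100 genes changed 2-fold and 34% of 100 changed 1.5-fold were recovered, and 5.71% of calls were false. For the DNMT3b comparison, over 16341 genes, the shares were 63% and 30%, with 12.3% of calls false. A simulated list of 40 genes raised 1.5-fold was found by camera in the DNMT3a comparison over 16297 genes, with 0 of 25 unchanged lists called, and also with an estimated correlation (adjusted p = 8.90e-05). Simulated genes were independent of each other, so this does not test the preset correlation, and estimated correlations of the real lists reached 0.889. The covariance that shared controls give the knockdowns' fold changes was estimated from 20 simulated draws in which unchanged groups met the same simulated controls, with library numbers ignored.

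Alternatives were size factors in place of TMM, library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, fits of only the 2 groups compared, the replicate block, a fold threshold of 2, and each of the 9 libraries left out in turn. Fits without all libraries numbered 2, and fry and the estimated correlation with the block, were added after the data were seen. Short sequence words were counted in annotated 3' untranslated regions (UTRs) of at least 50 bases, which 13492 of the tested genes had. Of the 16384 words of 7 bases, those common enough to test (15891 and 12803 for the genes that fell with DNMT3a and DNMT3b siRNA, 13937 and 12115 for those that rose) were each compared between a gene set and the remaining genes within 10 strata of UTR length and 5 of GC content, by a one-sided Mantel-Haenszel test with Benjamini-Hochberg adjustment.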

Results

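Cultured cells of embryonic mouse ventricles were given siRNA against Dnmt3a or Dnmt3b, whose enzymes place methyl groups on unmethylated DNA. They were sorted with the VCAM1 antibody only at harvest. Their transcripts were compared with those of cells given a negative control siRNA. The comparisons ask which genes differ once each transcript has been lowered, and neither protein nor DNA methylation was analysed here. Each of the 3 groups had 3 libraries. Reads counted in genes were 35896018, 31480073 and 27852412 in control 1, 2 and 3, 30878855, 31175409 and 30756749 in DNMT3a 1, 2 and 3, and 32628056, 31102332 and 28284399 in DNMT3b 1, 2 and 3. Between 23037 and 25190 genes had at least 1 count in a library, and the 10 most abundant genes took 9.13% to 11.4% of its counts. The abundant transcripts were not confined to heart muscle genes. Col1a1, a collagen of fibroblasts, averaged 23952 CPM in the controls, and Fn1, which encodes fibronectin, 21764 CPM, against 801 CPM for Tnnt2, the cardiac troponin T gene.

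Libraries differed within groups as well as between them. The first principal component of log2 CPM (31.6% of the variance) held control 2 at 10.7, apart from control 1 at -35.3 and control 3 at -30.9, and DNMT3a 2 at 11.6, apart from DNMT3a 1 at -28.5 and DNMT3a 3 at -17.5. The DNMT3b libraries lay at 16.4, 36.0 and 37.6 on it. The second component (24.1%) separated the groups, with DNMT3a libraries from -37.7 to -23.7, DNMT3b libraries from -1.3 to 7.7 and controls from 22.4 to 30.8. The closest replicates were DNMT3b 2 and 3, with a chi-square per degree of freedom of 6.42, and the farthest control 1 and 2, with 59.7.

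Each siRNA lowered its own target. Dnmt3a (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443, plus strand, GRCm38) was at 259 ± 23.2 CPM in controls (SD, n = 3; counts 7431 to 8338), 46.5 ± 6.32 CPM after DNMT3a siRNA (1241 to 1747) and 228 ± 11.4 CPM after DNMT3b siRNA (6698 to 7243). Its log2 fold change was -2.48 ± 0.11 with DNMT3a siRNA (adjusted p = 3.42e-06), which left 18.0% of the control level. It was -0.18 ± 0.11 with DNMT3b siRNA (adjusted p = 0.348). Dnmt3b (ENSMUSG00000027478, chromosome 2, 153649450 to 153687730, plus strand) was far less abundant, at 4.30 ± 0.0372 CPM in controls (117 to 155 counts), 4.76 ± 0.0964 CPM after DNMT3a siRNA and 1.70 ± 0.652 CPM after DNMT3b siRNA (38 to 75 counts). Its log2 fold change was -1.34 ± 0.23 with DNMT3b siRNA (adjusted p = 0.00816), or 39.5% of control, and 0.15 ± 0.22 with DNMT3a siRNA (adjusted p = 0.752). The Dnmt3b call ended without DNMT3b 3 (-1.28, adjusted p = 0.0538), and its adjusted p ran from 4.53e-06 to 0.0538 over the alternatives. Dnmt1, the maintenance methyltransferase (ENSMUSG00000004099, chromosome 9, 20907209 to 20959888, minus strand), stood at 144 ± 18.2 CPM in controls and did not pass in either knockdown (0.12 ± 0.11, adjusted p = 0.541, and -0.03 ± 0.11, adjusted p = 0.915).

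Vcam1, the gene of the protein on which the cells were sorted (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), was at 306 ± 47.8 CPM in controls, 229 ± 25.2 CPM after DNMT3a siRNA and 283 ± 20.6 CPM after DNMT3b siRNA. With DNMT3a siRNA its log2 fold change of -0.42 ± 0.12 missed the threshold (adjusted p = 0.0510) and passed in the blocked fit (adjusted p = 0.0234). It also passed without control 1 (0.0489), without control 2 (0.0406) or without DNMT3a 3 (0.0440), and its adjusted p ran from 0.00455 to 0.168 over the alternatives. With DNMT3b siRNA it was -0.11 ± 0.12 (adjusted p = 0.632).

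**Figure D1:**
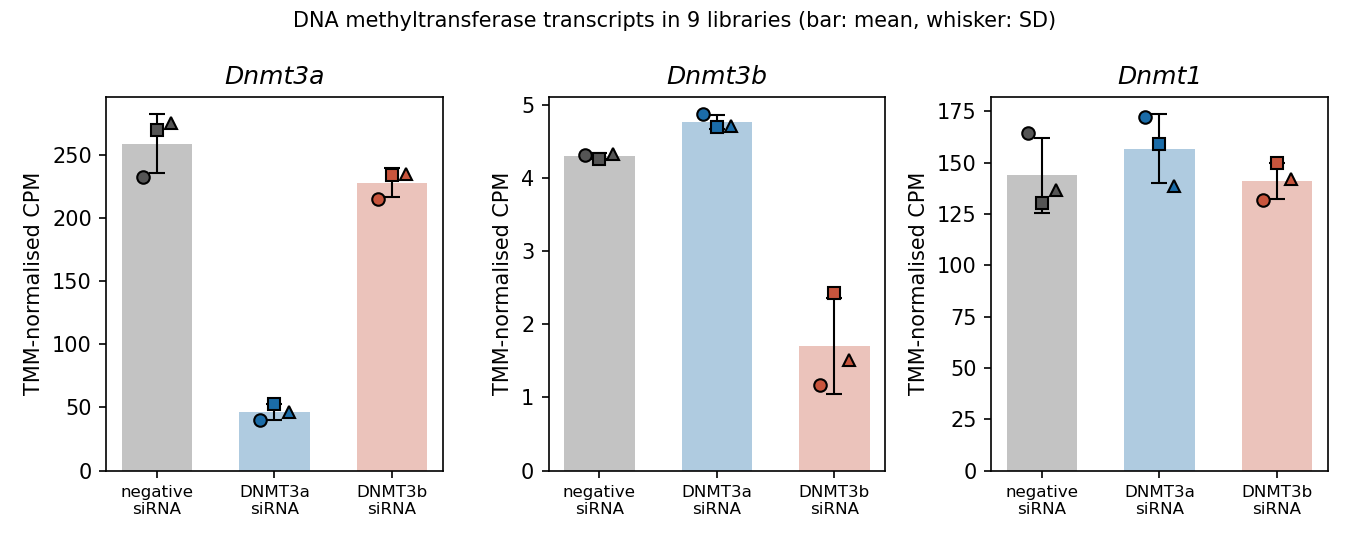
TMM-normalised CPM of Dnmt3a, Dnmt3b and Dnmt1 in the 3 groups, each on its own axis from 0; bars give the mean of 3 libraries, whiskers the SD, and points the libraries, with a circle, square or triangle for replicate 1, 2 or 3. Dnmt3a fell to 18.0% of control with DNMT3a siRNA and Dnmt3b to 39.5% with DNMT3b siRNA, while Dnmt1 passed the test in neither.

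After DNMT3a siRNA, genes of the heart muscle cell were higher than in controls. Nppb, which encodes brain natriuretic peptide (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205), rose 7.59-fold, from 7.20 ± 1.22 to 54.5 ± 4.37 CPM (n = 3 per group, log2 fold change 2.92 ± 0.15, adjusted p = 9.03e-06). Nmrk2, a nicotinamide riboside kinase of muscle (ENSMUSG00000004939, chromosome 10, 81198170 to 81202051), rose 10.6-fold from 1.12 ± 0.422 CPM (3.41 ± 0.24, adjusted p = 3.82e-05). Nkx2-5, a transcription factor of heart development (ENSMUSG00000015579, chromosome 17, 26838664 to 26845009), rose 3.02-fold from 14.6 ± 1.43 CPM (1.59 ± 0.11, adjusted p = 3.72e-05), and Myh6, the alpha cardiac myosin heavy chain (ENSMUSG00000040752, chromosome 14, 54941921 to 54966927), 2.33-fold from 768 ± 181 CPM (1.22 ± 0.18, adjusted p = 0.00266). Hmgcs1, an enzyme of cholesterol synthesis (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), was 3.53-fold lower (-1.82 ± 0.18, adjusted p = 3.95e-04).

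In all, 1671 of 16561 genes (10.1%) changed with DNMT3a siRNA, 807 higher and 864 lower, of which 288 and 167 by at least 2-fold. Genes whose 3 knockdown libraries all lay on 1 side of the 3 controls made up 26.7%, against 10% by chance. Scaling by library size alone called 1668 genes, 61.1% of them higher in place of 48.3%. Further large rises were those of Pirt (2.33 ± 0.24), Csrp3, a Z-disc protein of striated muscle (2.27 ± 0.32), Acta1, skeletal muscle actin (2.19 ± 0.36), and Inpp5j (2.07 ± 0.27). Large falls were those of Anxa8, an annexin (-2.28 ± 0.29), Clcn5, a chloride transporter (-2.05 ± 0.19), Tnxb, an extracellular matrix protein (-1.91 ± 0.24), and Prkcb, a protein kinase C (-1.84 ± 0.17). Without control 3, DNMT3a 1 or DNMT3a 3, the count of changed genes was 971, 868 and 1038.

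Heart muscle lists were higher as groups with DNMT3a siRNA. Of 44 measured sarcomere genes, 34 rose, 0 fell and 10 did not pass, with a median log2 fold change of 1.28. Adjusted over the list alone, 37 rose. Examples were Nebl, a nebulin-like protein of thin filaments (1.78 ± 0.12), Trim63, a muscle ubiquitin ligase (1.70 ± 0.12), Tnni3, cardiac troponin I (1.76 ± 0.23, adjusted p = 0.00188) and Tnnt2 (0.75 ± 0.13, adjusted p = 0.00509). The list passed camera (adjusted p = 1.30e-26; adjusted p = 0.328 with an estimated correlation). Of 44 calcium-handling and ion channel genes, 17 rose and 2 fell, and 23 rose and 3 fell adjusted over the list alone (median 0.63, adjusted p = 7.27e-08; adjusted p = 0.328 with an estimated correlation). The triadin gene Trdn rose 2.80-fold (1.48 ± 0.19) and the calcium channel gene Cacna1c 2.10-fold (1.07 ± 0.14).

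Of 34 cardiac transcription factor genes, 8 rose and 0 fell with DNMT3a siRNA, and 16 rose and 1 fell adjusted over the list alone (median 0.35, adjusted p = 1.99e-06; adjusted p = 0.328 with an estimated correlation). Besides Nkx2-5, Smyd1, a muscle methyltransferase (1.18 ± 0.16), Tbx3 (0.75 ± 0.14) and Tbx18 (0.50 ± 0.10) rose. Without DNMT3a 3, 5 members rose. Gata4 did not pass (0.25 ± 0.08, adjusted p = 0.0755, range 0.0432 to 0.252 over the alternatives). Of 21 natriuretic and load-response genes, 7 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (median 0.21, adjusted p = 9.98e-05; adjusted p = 0.328 with an estimated correlation). Nppa, atrial natriuretic peptide, rose 4.22-fold (2.08 ± 0.22, adjusted p = 8.07e-04) and Xirp1, a protein of intercalated discs, 3.35-fold (1.74 ± 0.17). Myh7, the beta myosin heavy chain, was at 90.1 ± 65.2 CPM in controls and 178 ± 47.4 CPM after DNMT3a siRNA (0.98 ± 0.47, adjusted p = 0.251). Control 2 held 165 CPM of it against 45.2 and 60.3 CPM in control 1 and 3, and without control 2 Myh7 passed (1.75, adjusted p = 0.00262; range over the alternatives 0.00262 to 0.515).

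Among metabolic lists with DNMT3a siRNA, 11 of 50 respiratory-chain genes rose and 0 fell, and 16 rose adjusted over the list alone (median 0.25, adjusted p = 1.19e-07; adjusted p = 0.594 with an estimated correlation), among them Ndufv1, a subunit of complex I (0.47 ± 0.08). Leaving out 1 library moved that count to 4 (control 1), 2 (control 3), 2 (DNMT3a 1), 3 (DNMT3a 2), 7 (DNMT3b 1), 4 (DNMT3b 2) and 5 (DNMT3b 3). Of 31 fatty acid oxidation genes, 4 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone (median 0.20, adjusted p = 0.00113; adjusted p = 0.568 with an estimated correlation). The count of risen members was 7 in the blocked fit and 2 without control 3. Ppargc1a and Ppargc1b, which encode coactivators of mitochondrial genes, rose by 1.35 ± 0.25 and 1.08 ± 0.13. Glycolysis and hypoxia genes did not pass as a list (36 measured, 6 rose, 1 fell, or 3 in the blocked fit, adjusted p = 0.937). Adjusted over the list alone, 6 rose and 4 fell. Its median was -0.12 and its mean -0.08 while the test pointed up. Without control 2 it passed upward with 10 members risen (adjusted p = 2.65e-04), and without control 3 it had 3 risen. Pgam2, a muscle phosphoglycerate mutase, rose by 1.40 ± 0.22.

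Of 24 cholesterol synthesis genes, 0 rose and 5 fell with DNMT3a siRNA, and 14 fell adjusted over the list alone (median -0.46, adjusted p = 1.17e-07; adjusted p = 0.568 with an estimated correlation). In the blocked fit 10 fell. In turn, 11 fell without control 2, 2 without DNMT3a 2 and 2 without DNMT3a 3. Besides Hmgcs1, Insig1 (-1.40 ± 0.29, adjusted p = 0.0212) and Sqle (-0.81 ± 0.18, adjusted p = 0.0190) fell. Neither passed without DNMT3a 2 (adjusted p = 0.0659 and 0.0502) or DNMT3a 3 (0.0797 and 0.0641). Their adjusted p over the alternatives ran over 1.42e-06 to 0.0814 and 1.30e-04 to 0.0641. The 3' UTRs of Hmgcs1, Insig1 and Sqle each held the 7-base word GCCAATA, which 30.0% of genes lower with DNMT3a siRNA than in both other groups held, against 4.36% of other genes.

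Markers of other cell types moved by different amounts with DNMT3a siRNA. Of 18 macrophage and leukocyte genes, 0 rose and 4 fell, and 13 fell adjusted over the list alone (median -1.71, adjusted p = 2.72e-07; adjusted p = 0.568 with an estimated correlation). In the blocked fit 16 fell, and 8, 1 and 2 fell without control 1, control 3 and DNMT3a 1. Mpeg1, a macrophage pore protein, fell by 2.29 (SE 0.48, adjusted p = 0.0182, range 1.77e-06 to 0.0956 over the alternatives). On this list's level control 1 stood at -0.35, below DNMT3a 3 at -0.28 and apart from control 2 and 3 at 1.13 and 1.34. The groups thus overlapped when library numbers were ignored. Within each number the level was lower after DNMT3a siRNA: -1.97 against -0.35, -0.49 against 1.13 and -0.28 against 1.34 for numbers 1, 2 and 3. These genes were scarce: C1qa, a complement gene of macrophages, averaged 5.14 CPM in controls and 1.14 CPM after DNMT3a siRNA. Of 30 fibroblast and matrix genes, 4 fell and 0 rose, the same adjusted over the list alone (median -0.14, adjusted p = 0.00991; adjusted p = 0.459 with an estimated correlation), among them Fbn1, fibrillin (-0.58 ± 0.10), and Tcf21 (-0.71 ± 0.11). That call ended without control 2 (0.0870) or DNMT3a 2 (0.0806).

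Of 16 epicardial genes, 2 rose and 5 fell with DNMT3a siRNA, the same adjusted over the list alone (median -0.34, adjusted p = 0.0198; adjusted p = 0.594 with an estimated correlation). The call ended in the blocked fit (0.0505) and without DNMT3a 1 (0.0901), and 3 fell without control 1, control 3, DNMT3a 1 or DNMT3a 2. Aldh1a2, an enzyme of retinoic acid synthesis, was 2.88-fold lower, from 71.9 ± 13.5 CPM in controls (-1.52 ± 0.18, adjusted p = 9.10e-04). Of 16 smooth muscle and pericyte genes, which embryonic cardiomyocytes partly share, 1 rose, 4 in the blocked fit and 1 adjusted over the list alone (median 0.38, adjusted p = 0.0198; adjusted p = 0.594 with an estimated correlation). The call ended without control 1 (0.159) or DNMT3a 2 (0.0806). Endothelial and endocardial genes (20 measured, 0 changed, adjusted p = 0.649) and Schwann and neural genes (8 measured, 0 changed, adjusted p = 0.803) did not pass.

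Lists close to DNA methylation did not pass camera with DNMT3a siRNA, although fry called the methylation machinery, which includes the siRNA's target, lower (adjusted p = 0.00558). Of 20 genes of the methylation machinery 2 fell (adjusted p = 0.649), Dnmt3a itself and Mbd1, a reader of methylated DNA (-0.75 ± 0.17, adjusted p = 0.0201). Mbd1 did not pass without control 3 (0.0730), DNMT3a 1 (0.0732) or DNMT3a 3 (0.0597), and its adjusted p ran from 3.02e-04 to 0.0732 over the alternatives. The list's median was 0.04, its mean -0.13 and its test pointed down. Of 13 germline genes known as targets of methylation, 1 rose and 1 fell (adjusted p = 0.803): Mov10l1 (1.66 ± 0.34) and Ddx4, whose counts were 22 to 51 in controls and 0 to 3 after DNMT3a siRNA. Of 37 imprinted genes 2 rose, Copg2 among them (0.43 ± 0.08), and 1 fell, or 5 in the blocked fit (adjusted p = 0.625; median 0.01, mean -0.07, test down). Hox and Polycomb target genes (18 measured, 0 rose, 1 fell, 3 in the blocked fit) had an adjusted p of 0.691.

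The remaining lists did not pass with DNMT3a siRNA. Cell cycle genes (51 measured, 1 rose, 3 fell) had an adjusted p of 0.649; Mcm7, a replication helicase subunit whose 3' UTR holds GCCAATA, fell by 0.84 (SE 0.14). Inflammatory genes (19 measured, 1 rose, 2 fell; 3 and 4 in the blocked fit) missed the threshold narrowly (adjusted p = 0.0509). Interferon genes (37 measured, 1 rose, 1 fell, 3 fell in the blocked fit) had an adjusted p of 0.290, stress-response genes of the unfolded protein pathway (28, 1 and 1, 3 rose in the blocked fit) 0.685, and p53 and apoptosis genes (27, 1 and 1, 2 rose in the blocked fit) 0.248. Genes of the siRNA machinery (13, 1 rose, 2 fell, Ago3 at -0.56 ± 0.11) had 0.649, housekeeping genes (18, 1 and 2) 0.290, and sex-linked genes (5, 0 and 1) 0.803. Inflammatory genes passed when scaled by library size alone (0.0313) and without control 1 (0.00134), DNMT3a 3 (0.00997) or DNMT3b 1 (0.0446), and cell cycle genes without control 1 (0.00946) or DNMT3a 3 (0.0434). Interferon genes passed without control 2 (4.00e-04), DNMT3a 1 (0.0222) or DNMT3a 3 (0.0236), and p53 genes without control 2 (0.0202). In these lists, leaving out 1 library gave 0 to 3 members risen and 0 to 3 fallen.

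**Figure D2:**
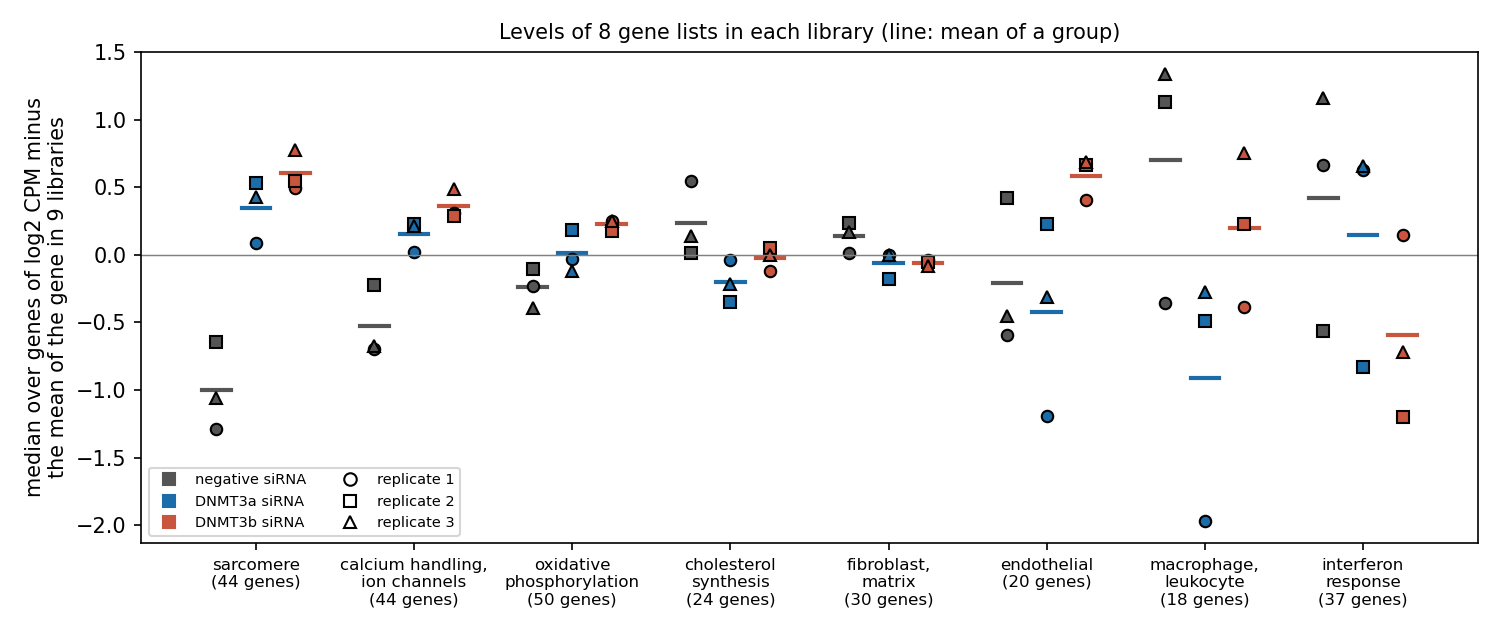
Level of 8 gene lists in each of the 9 libraries, as the median over a list's genes of log2 CPM minus the gene's mean in all libraries; colours give the groups, shapes the replicate numbers and lines the group means. Sarcomere genes lay between -1.29 and -0.65 in the controls and between 0.09 and 0.78 in the knockdown libraries.

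After DNMT3b siRNA, heart muscle genes were again higher than in controls. Hopx, a homeodomain protein of the heart (ENSMUSG00000059325, chromosome 5, 77086988 to 77115121), rose 5.53-fold from 4.26 ± 1.69 to 23.5 ± 3.56 CPM (n = 3 per group, 2.47 ± 0.37, adjusted p = 0.00680). Nppa rose 4.72-fold (2.24 ± 0.22, adjusted p = 8.70e-04), Tnni3 (ENSMUSG00000035458, chromosome 7, 4518305 to 4524229) 4.04-fold (2.01 ± 0.23, adjusted p = 0.00154), Nkx2-5 2.90-fold (1.54 ± 0.11, adjusted p = 5.69e-05) and Myh6 2.61-fold (1.38 ± 0.18, adjusted p = 0.00218). Cxcl1, a chemokine (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), rose 4.54-fold from a low level of 0.793 ± 0.143 to 3.59 ± 0.593 CPM (2.18 ± 0.26, adjusted p = 9.58e-04). The largest fall by the naming rule was that of Cdkn2aipnl (ENSMUSG00000020392, chromosome 11, 51967661 to 51977334), 3.47-fold lower (-1.79 ± 0.14, adjusted p = 1.48e-04).

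In all, 934 genes changed with DNMT3b siRNA, 583 higher and 351 lower, of which 295 and 55 by at least 2-fold. Genes with all 3 knockdown libraries on 1 side of the controls made up 26.1%, against 10% by chance. Other large rises were those of Pirt (2.25 ± 0.24), Lmod3, a leiomodin (2.25 ± 0.22), Adprhl1 (2.20 ± 0.21) and Aqp4, a water channel (2.17 ± 0.33). Other large falls were those of Tnxb (-1.76 ± 0.24), Olr1, a scavenger receptor (-1.60 ± 0.25), Cmklr1, a chemoattractant receptor (-1.54 ± 0.16), Pid1 (-1.47 ± 0.20) and Sema3e, a semaphorin (-1.41 ± 0.13). The 3' UTRs of Olr1, Pid1 and Sema3e held the 7-base word GCATGTA. Of searched genes lower with DNMT3b siRNA than in both other groups, 24.1% held it, against 8.01% of other genes. The word was picked for standing out in those lower genes. The count of changed genes was 534, 1781 and 449 without control 1, 2 and 3, 384 without DNMT3b 2 and 287 without DNMT3b 3. DESeq2 called 1715 genes.

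With DNMT3b siRNA, 34 of 44 sarcomere genes rose and 0 fell, and 41 rose adjusted over the list alone (median 1.68, adjusted p = 1.82e-37; adjusted p = 0.159 with an estimated correlation). Nebl rose by 2.07 ± 0.12, Lmod2 by 2.05 ± 0.16 and Tnnt2 by 1.00 ± 0.13. Of 44 calcium-handling and ion channel genes, 21 rose and 1 fell, and 27 rose and 2 fell adjusted over the list alone (median 0.99, adjusted p = 8.91e-13; adjusted p = 0.159 with an estimated correlation). The count was 13 without control 3 and 10 without DNMT3b 3. Ryr2, the calcium release channel of the sarcoplasmic reticulum, rose 3.61-fold (1.85 ± 0.17), and Casq2, cardiac calsequestrin, 3.88-fold (1.96 ± 0.21). Of 21 natriuretic and load-response genes, 9 rose and 0 fell, and 12 rose and 1 fell adjusted over the list alone (median 0.60, adjusted p = 2.00e-07; adjusted p = 0.159 with an estimated correlation). Nppb rose 3.58-fold (1.84 ± 0.15), and Rcan1 by 1.30 ± 0.19. Of 34 cardiac transcription factor genes, 5 rose, 0 fell and 29 did not pass, and 9 rose and 1 fell adjusted over the list alone (median 0.06, adjusted p = 0.01003; adjusted p = 0.382 with an estimated correlation). Smyd1 rose by 1.69 ± 0.16 and Myocd by 1.00 ± 0.14, and 8 members rose without DNMT3a 3. Gata4 did not pass (0.04 ± 0.08, adjusted p = 0.829), nor did Myh7 (1.68 ± 0.48, adjusted p = 0.0914), which passed without control 2 (2.46, adjusted p = 7.27e-04; range over the alternatives 4.84e-04 to 0.271).

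Lists of energy metabolism were higher with DNMT3b siRNA and the cholesterol list lower. Of 50 respiratory-chain genes, 31 rose and 0 fell, and 45 rose adjusted over the list alone (median 0.48, adjusted p = 8.79e-23; adjusted p = 0.322 with an estimated correlation). Among them were Uqcrfs1 (0.56 ± 0.07), Cox8a (0.66 ± 0.11) and Cox7a1, a heart and muscle subunit (1.83 ± 0.30). Without control 1, control 3, DNMT3b 2 and DNMT3b 3 the count was 12, 9, 13 and 4. Of 31 fatty acid oxidation genes, 9 rose and 1 fell, and 20 rose and 1 fell adjusted over the list alone (median 0.34, adjusted p = 9.35e-11; adjusted p = 0.159 with an estimated correlation). Acadl, an acyl-CoA dehydrogenase, rose by 1.00 ± 0.13, Esrrg, a nuclear receptor, by 1.30 ± 0.19 and Ppargc1a by 1.56 ± 0.25. Risen members numbered 5 without control 1, control 3 or DNMT3b 2, 14 without control 2 and 4 without DNMT3b 3. Of 36 glycolysis and hypoxia genes, 6 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (median 0.28, adjusted p = 8.44e-05; adjusted p = 0.531 with an estimated correlation). Eno3, muscle enolase, rose by 1.21 ± 0.18. Control 2 lay at 0.66 on this list's level, against -0.57 and -0.31 in control 1 and 3. Without control 2, 26 members rose, and 3, 2, 3 and 2 rose without control 1, control 3, DNMT3b 2 and DNMT3b 3. Of 24 cholesterol synthesis genes 2 fell, also adjusted over the list alone (median -0.33, adjusted p = 1.14e-04; adjusted p = 0.528 with an estimated correlation): Hmgcs1 (-0.71 ± 0.18, adjusted p = 0.0441) and Hsd17b7 (-0.81 ± 0.20, adjusted p = 0.0469). Neither passed without control 1 (adjusted p = 0.0579 and 0.0828), control 3 (0.0613 and 0.111), DNMT3a 1 (0.0625 and 0.0545), DNMT3b 1 (0.0969 and 0.1001), DNMT3b 2 (0.139 and 0.141) or DNMT3b 3 (0.160 and 0.174). Hmgcs1 also did not without DNMT3a 2 (0.0537) or Hsd17b7 without DNMT3a 3 (0.0726). Their adjusted p ran from 0.00148 to 0.160 and from 0.00152 to 0.174 over the alternatives.

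Markers of other cell types moved in both directions with DNMT3b siRNA. Of 20 endothelial and endocardial genes, 1 rose, also adjusted over the list alone (median 0.69, adjusted p = 6.76e-04; adjusted p = 0.483 with an estimated correlation). The count was 4 without control 2 and 0 without control 1, control 3 or any DNMT3b library. Cdh5, VE-cadherin, averaged 16.3 CPM in controls and 30.9 CPM after DNMT3b siRNA and did not pass (adjusted p = 0.332). Control 2 stood apart on this list, at 0.42 against -0.60 and -0.45 in control 1 and 3, and above DNMT3b 1 at 0.41. Of 16 smooth muscle and pericyte genes 0 changed, and 6 rose and 1 fell adjusted over the list alone (median 0.52, adjusted p = 9.54e-04; adjusted p = 0.469 with an estimated correlation); 6 rose without control 2. Of 30 fibroblast and matrix genes, 5 fell and 0 rose, the same adjusted over the list alone (median -0.19, adjusted p = 4.60e-04; adjusted p = 0.210 with an estimated correlation). In turn, 1, 0, 1 and 0 fell without control 1, control 3, DNMT3b 2 and DNMT3b 3. Of 16 epicardial genes, 2 rose and 3 fell, and 3 rose and 7 fell adjusted over the list alone (median -0.47, adjusted p = 0.0222; adjusted p = 0.519 with an estimated correlation). The call ended without DNMT3b 3 (0.0811), and 1, 6, 0, 7, 0 and 0 fell without control 1, control 2, control 3, DNMT3b 1, DNMT3b 2 and DNMT3b 3. Clu, clusterin, rose from 337 ± 120 to 1101 ± 91.9 CPM (1.71 ± 0.24, adjusted p = 0.00431). Macrophage and leukocyte genes (18 measured, 0 changed, median -0.61) missed the threshold (adjusted p = 0.0654) and passed without control 1 (1.98e-05), DNMT3a 1 (0.0254), DNMT3b 2 (0.0486) or DNMT3b 3 (0.0111), and when scaled by library size alone (0.0336). Schwann and neural genes did not pass (8 measured, 0 changed, adjusted p = 0.767).

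Of 19 inflammatory genes, 3 rose and 0 fell with DNMT3b siRNA, and 6 rose adjusted over the list alone (median 0.22, adjusted p = 0.00247; adjusted p = 0.483 with an estimated correlation), Cxcl1 among them; 6 rose without control 2 and 1 without DNMT3b 3. The interferon list was lower (37 measured, 1 rose, 0 fell, also adjusted over the list alone; median -1.07, adjusted p = 7.04e-06; adjusted p = 0.531 with an estimated correlation). The riser, Ifi27 (0.75 ± 0.14, adjusted p = 0.00937), an interferon-induced mitochondrial protein, did not pass without DNMT3b 3 (0.0502; range 9.47e-06 to 0.0502 over the alternatives). The list's level was -0.56 in control 2 against 0.66 and 1.16 in control 1 and 3, so that the controls spread more widely than the groups differed. Of 28 stress-response genes, 2 fell and 0 rose, and 3 fell adjusted over the list alone (median -0.17, adjusted p = 1.99e-04; adjusted p = 0.5003 with an estimated correlation), among them Mthfd2, an enzyme of mitochondrial folate metabolism (-0.81 ± 0.11, adjusted p = 0.00262). The count was 12 without DNMT3b 1, and 1 without control 3, DNMT3b 2 or DNMT3b 3.

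Among lists close to DNA methylation with DNMT3b siRNA, 2 of 20 genes of the methylation machinery fell, Dnmt3b itself and Mbd1 (-1.06 ± 0.17, adjusted p = 0.00616), and the list did not pass camera (adjusted p = 0.136) but was called lower by fry (adjusted p = 0.00646). Imprinted genes (37 measured, 2 rose, 1 fell) had an adjusted p of 0.143, with Ddc at 0.95 ± 0.15, and germline genes (13, 1 and 0; median -0.17, mean 0.10, test down) and Hox and Polycomb targets (18, 0 and 0) 0.767 each. Cell cycle genes (51, 0 and 1) had 0.440, p53 and apoptosis genes (27, 1 and 0) 0.309, genes of the siRNA machinery (13, 0 and 1) 0.0679, housekeeping genes (18, 2 and 1; median -0.05, mean 0.04, test up) 0.780 and sex-linked genes (5, 0 and 0) 0.767. Cell cycle genes passed without control 1 (0.00225), and without control 2 p53 genes (0.0465) and the siRNA machinery (0.0158) did.

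The knockdowns were also compared with each other, which tests whether their effects differ. Dnmt3a was lower (-2.29 ± 0.11, adjusted p = 7.29e-06) and Dnmt3b higher (1.48 ± 0.23, adjusted p = 0.00431) after DNMT3a siRNA than after DNMT3b siRNA. Sult4a1, a sulfotransferase whose 3' UTR holds GCCAATA, was higher by 2.28 ± 0.23 (adjusted p = 4.65e-04), Nmrk2 by 1.75 ± 0.22 (adjusted p = 0.00137) and Cdkn2aipnl by 1.70 ± 0.14 (adjusted p = 2.48e-04). Of the 11 genes past the threshold that the naming rule gave here, 5 kept their call in every alternative. The other 6, Cd34, H2-T23, C3, Sprr1a, Rtn4rl2 and Lrrn2, did not. Of the natriuretic and load-response genes (21 measured, 1 higher, 3 lower, adjusted p = 0.637), Nppb was higher (1.09 ± 0.14, adjusted p = 0.00170), and Rcan1 (-1.12), Ccn2 (-0.54) and Cryab (-0.26) lower, all chosen after their values were seen. The count of lower members was 1 without DNMT3a 3, DNMT3b 2 or DNMT3b 3. The other heart genes fixed in advance did not pass: Myh6 differed by -0.17 ± 0.18 (adjusted p = 0.611), Tnnt2 by -0.26 ± 0.13 (0.237), Tnni3 by -0.26 ± 0.22 (0.501), Nppa by -0.16 ± 0.21 (0.690), Nkx2-5 by 0.06 ± 0.10 (0.775), Gata4 by 0.21 ± 0.08 (0.127), Myh7 by -0.70 ± 0.47 (0.395, range 0.0197 to 0.676 over the alternatives) and Vcam1 by -0.30 ± 0.12 (0.140).

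In all, 1582 genes differed between the knockdowns, 741 higher and 841 lower after DNMT3a siRNA, of which 116 and 195 by at least 2-fold. In 32.3% of genes the groups did not overlap, against 10% by chance. Without DNMT3a 1, DNMT3a 3, DNMT3b 2 and DNMT3b 3 the count was 541, 768, 524 and 555. Lower after DNMT3a siRNA were the lists of inflammatory genes (1 higher, 6 lower of 19, adjusted p = 1.01e-05; adjusted p = 0.748 with an estimated correlation; 3 lower without DNMT3b 2), respiratory-chain genes (0 and 5 of 50, adjusted p = 2.72e-06; adjusted p = 0.868 with an estimated correlation), and fatty acid oxidation genes (1 and 4 of 31, adjusted p = 0.00215; adjusted p = 0.748 with an estimated correlation). For the respiratory chain the count of lower members was 1 without DNMT3a 1, DNMT3a 3 or DNMT3b 2, 12 without DNMT3a 2, 2 without DNMT3b 1 and 0 without DNMT3b 3. For fatty acid oxidation it was 1 without DNMT3a 1 or DNMT3b 3 and 2 without DNMT3a 3, DNMT3b 1 or DNMT3b 2. Also lower were glycolysis genes (0 and 2 of 36, adjusted p = 5.05e-04; adjusted p = 0.897 with an estimated correlation), endothelial genes (0 and 1 of 20, adjusted p = 4.67e-04; adjusted p = 0.748 with an estimated correlation) and leukocyte genes (0 and 0 of 18, adjusted p = 4.15e-04; adjusted p = 0.868 with an estimated correlation). Lower glycolysis genes numbered 5 without control 1, 12 without control 2 and 1 without DNMT3a 1, DNMT3a 3 or any DNMT3b library, and lower endothelial genes 2 without control 1 or 2, 8 without DNMT3a 2 and 0 without DNMT3a 1, DNMT3a 3, DNMT3b 2 or DNMT3b 3.

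Stress-response genes were higher as a list after DNMT3a than after DNMT3b siRNA (4 higher and 1 lower of 28, adjusted p = 1.60e-04; adjusted p = 0.748 with an estimated correlation). Higher members numbered 14 without DNMT3b 1 and 2 without DNMT3a 1, DNMT3a 3, DNMT3b 2 or DNMT3b 3. Adjusted over the list alone, 10 stress-response genes were higher, 11 inflammatory and 8 fatty acid oxidation genes lower, and 0 sarcomere genes differed. Sarcomere genes were lower as a list (median -0.30, adjusted p = 0.00721; adjusted p = 0.897 with an estimated correlation), although the 2 of 44 members that differed, Fhod3 (0.42) and Nexn (0.33), both proteins of cardiac filaments chosen after their values were seen, were higher. That contrast changed when 1 library was left out. Higher members numbered 0 without DNMT3a 1, DNMT3a 3, DNMT3b 1 or DNMT3b 2 and 1 without DNMT3a 2 or DNMT3b 3. Lower members numbered 4 without control 2 or DNMT3a 2 and 1 without control 1 or DNMT3b 2. Without DNMT3a 1, DNMT3a 3, DNMT3b 1 or DNMT3b 2, all calls between the knockdowns also fell, from 1582 to 541, 768, 1088 and 524. The sarcomere list's call ended without DNMT3a 1 (0.0809) or DNMT3b 3 (0.0956). The calls of 4 lists ended when single libraries were left out, each adjusted p with an estimated correlation being at least 0.748. Interferon genes (higher, 0 and 0 of 37, adjusted p = 0.00406) did not pass without DNMT3a 1 (0.0871), DNMT3a 3 (0.112) or DNMT3b 2 (0.104). Cardiac transcription factors (higher, 1 and 0 of 34, adjusted p = 0.0454) did not without DNMT3a 1 (0.0871), DNMT3a 3 (0.127), DNMT3b 1 (0.158) or DNMT3b 2 (0.104), nor with the filter of 1 CPM (0.0503). Imprinted genes (lower, 1 and 4 of 37, adjusted p = 0.0454) did not without DNMT3a 1 (0.116), DNMT3a 3 (0.0610) or DNMT3b 2 (0.104), each of which left 0 members lower, while 2 were lower without DNMT3b 1 and 1 without DNMT3b 3. Cholesterol synthesis genes (lower, 0 and 2 of 24, adjusted p = 0.0454) did not without DNMT3a 2 (0.331), DNMT3a 3 (0.112), DNMT3b 2 (0.153) or DNMT3b 3 (0.0730). In these 4 lists, leaving out 1 library gave 0 to 3 higher members. The other 14 lists did not pass, calcium-handling genes among them (1 and 3 of 44, adjusted p = 0.0962, or 0.0463 with the filter of 1 CPM), and their adjusted p reached 0.888. Among them the germline list had a median of 0.19 and a mean of -0.35 with the test pointing up, while the cell cycle list had a median and mean of 0.01 and 0.00 with the test pointing down.

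Both knockdowns changed 414 genes in the same direction, 315 higher and 99 lower, and 15 in opposite directions. The shared calls were 44.3% of those made with DNMT3b siRNA, and lists drawn independently, without shared controls, would share 28.4 higher and 18.3 lower. The count was 261, 723 and 211 without control 1, 2 and 3, 233 without DNMT3b 2 and 190 without DNMT3b 3. Across genes, which are not independent replicates, log2 fold changes of the knockdowns correlated with r = 0.520, against 0.498 on average in 20 simulations with shared controls and no effect. Their covariance was 0.115, against 0.0386 simulated, a difference of 0.0767. Genes of equal sign made up 64.1%, against 66.7% simulated, so this measure showed no excess. The simulated libraries were drawn without regard to their numbers, which leaves out the pairing of DNMT3a with control libraries. Simulated genes were also independent of each other. The draws therefore do not show how far control deviations shared by many genes would move these measures. The 3 controls cannot be split into sets of 2, so part of the shared calls may come from the shared controls.

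**Figure D3:**
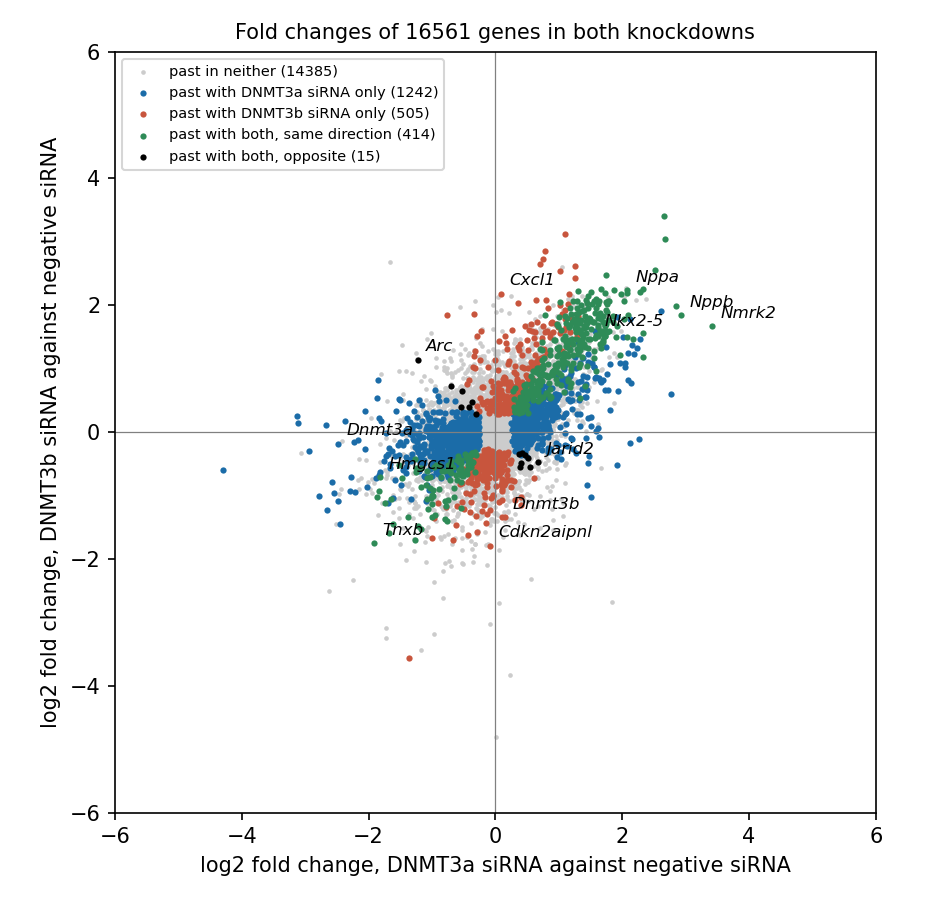
Log2 fold change against control of each of the 16561 genes after DNMT3a siRNA (horizontal) and DNMT3b siRNA (vertical), on axes of equal range with 1 gene outside; colours mark the genes that changed in neither, in 1 or in both knockdowns. Of the genes changed in both, 414 lie in the quadrants of equal sign and 15 in the others.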

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

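The tests of a higher share of cardiomyocytes and of genes detected were chosen only after those results were seen, while the tests of other cell types, of gene length and GC content, and of 3' UTR words were chosen before.

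In 15 genes the knockdowns moved expression in opposite directions against the shared controls, each past the threshold in both. They were chosen by those calls, so a test of their difference adds no independent support. Their adjusted p ran from 0.00276 (Jarid2) to 0.0376 (1810037I17Rik) with DNMT3a siRNA. With DNMT3b siRNA it ran from 0.00247 (Tmem65) to 0.0454 (Qsox2). The number that independent lists would give was not worked out, so 15 is read neither as an excess nor as a shortfall. As log2 fold changes between DNMT3a and DNMT3b siRNA, lower after DNMT3a siRNA were Arc (-2.36), Rcan2 (-1.42), Psen2 (-1.17), Errfi1 (-0.93), 1810037I17Rik (-0.85), Prkaca (-0.81) and Tmem39a (-0.60). Higher were, among others, Jarid2 (1.15), Frmd4b (1.10), AU040320 (0.93), Tmem65 (0.93), Rab11fip5 (0.82), Qsox2 (0.75) and ENSMUSG00000098148 (0.72). Arc, an immediate early gene, stood at -1.22 with DNMT3a and 1.14 with DNMT3b siRNA, and Jarid2, a Polycomb partner protein, at 0.68 and -0.47.

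Sarcomere genes rose in both knockdowns, and the sorted cells may have held different shares of cell types. Both rises were taken against the same 3 controls, so low levels in those libraries cannot be told apart from a rise. If fewer other cells were the cause, with each type lost in equal proportion, the 5 lists of other cell types should have fallen together. Types lost unequally would not do so, so this test cannot tell whether fewer other cells were the cause. By permutation of list membership (100000 permutations) the 5 lists differed from each other with p = 1e-05 in each knockdown, the smallest p possible. That permutation treats genes as independent, although the estimated correlation within the leukocyte list was 0.80. Its p therefore does not measure the spread between libraries. Medians for leukocyte, epicardial, endothelial, fibroblast and smooth muscle genes were -1.71, -0.34, -0.15, -0.14 and 0.38 with DNMT3a siRNA. Only the list that cardiomyocytes partly share was higher there. With DNMT3b siRNA the medians were -0.61, -0.47, 0.69, -0.19 and 0.52. A trend in gene length and GC content left medians of 1.24 (replicate block, DNMT3a) and 1.61 (DNMT3b), near 1.28 and 1.68 before. If more cardiomyocytes were the whole cause, all cardiomyocyte-restricted genes should move alike. With DNMT3a siRNA 4 of 26 departed from their median, 3 higher and 1 lower. With DNMT3b siRNA 3 of 26 did, all lower. Among them was Myl7 (log2 fold change 0.05 and -0.09, against medians of 1.29 and 1.79 over the 26 genes). For the genes that departed, a higher share alone would not give these values. The remaining genes showed no departure, which a higher share or a change within the cells would both give. For them these causes cannot be told apart here, and a higher share may have added to the rise.

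Among the 460 genes lower with DNMT3a siRNA than in both other groups, 433 had a 3' UTR to search. The word GCCAATA stood in 130 of them (30.0%) against 4.36% of other genes, the smallest adjusted p of any word (4.28e-89, stratified z test), and none of 192 risen genes' words passed (lowest adjusted p 0.0668). Such a word is what matches of an siRNA's seed (its bases 2 to 8) to unintended transcripts would leave, so part of the fall may be off-target; of 699 genes with the word 26.9% fell with DNMT3a siRNA (4.93% without it) and 4.72% with DNMT3b siRNA (2.39% without it). For the fallen genes 15 words passed, some of them shifts of each other. With GCGTTTA, picked after the result was seen, 37.4% of the fallen genes held at least 1 of the 2 words, against 5.71% of other genes. Both words were picked for standing out in these same genes, so 37.4% does not measure an off-target share. For the same reason, the 26.9% of genes with GCCAATA that fell adds no support beyond the test over all words. GCCAATA and GCGTTTA each occur in Dnmt3a transcripts, which a seed aimed at Dnmt3a would match, and not in Dnmt3b transcripts. Of all 7-base words, 52.7% occur in Dnmt3a and 24.7% in Dnmt3b transcripts, so this separates little. The siRNA sequences are not given in the sources used here, so a natural small RNA with the same seed stays open.

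In DNMT3a 2 and 3 and DNMT3b 2 and 3, 24718 to 25190 genes were detected, against 23037 to 24204 in the other 5 libraries. The number followed the share of reads outside annotated exons (Pearson r = 0.823 across 9 libraries, exact permutation p = 0.00898, adjusted over 2 tests 0.018), so more unspliced or intergenic RNA or genomic DNA may have raised it. It did not follow library depth (r = -0.0694, permutation p = 0.871). No biological explanation was tested.

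Group labels were also reassigned among the 6 libraries of each comparison. Of 10 splits into 3 and 3, the real split alone called as many genes in each comparison (1 of 10 in all 3), with 1671, 934 and 1582 genes against at most 0 in any other. Of the splits that part every pair in the DNMT3a comparison, 4 in number, the highest other also called 0. A set of 10 splits is too few for a share under 0.05. Every other split mixes the 2 groups, which widens the spread within each side. Any difference between the groups, technical or not, would therefore leave few calls there.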

How the results depend on the processing

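The fits without all libraries numbered 2, and the block combined with fry or an estimated correlation, were chosen only after the results were seen. Dnmt3a fell with DNMT3a siRNA under every alternative. Of 83 named or listed genes past the threshold with DNMT3a siRNA, 45 kept the call under every alternative, as did 47 of 72 with DNMT3b siRNA. How depth limits the calls was not tested.

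DESeq2 called 1715 genes with DNMT3b siRNA and 643 shared calls, and fits of only the 2 groups compared 946 with DNMT3a siRNA. At a fold change of at least 2, 455, 350 and 311 genes remained with DNMT3a siRNA, DNMT3b siRNA and between them. Without all libraries numbered 2 the counts were 1290, 1266 and 1529. No list passed with an estimated correlation (0, 0 and 0). With fry 7, 8 and 0 lists passed. It ended the DNMT3a calls of the respiratory chain, leukocyte, cholesterol, epicardial and smooth muscle lists (adjusted p 0.0889 to 0.160). It ended the DNMT3b calls of the glycolysis, smooth muscle, endothelial, epicardial, interferon, inflammatory, stress-response and cholesterol lists (0.0707 to 0.328). The cause was not tested.

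With a replicate block, 2370 genes changed with DNMT3a siRNA, and apart from the changes given beside those results the block changed no other call of a named gene or list with DNMT3a siRNA. In the comparisons that were not read as paired, the block gave 1801 genes with DNMT3b siRNA and 2513 between the knockdowns, with 662 shared calls. With DNMT3b siRNA the epicardial list no longer passed (adjusted p = 0.0550), while the leukocyte list (4.13e-04) and Myh7 (0.0383) did. Between the knockdowns the cardiac transcription factor and cholesterol lists no longer passed (0.0528 each). Same-numbered DNMT3b and control libraries correlated with r = 0.212, 0.101 and 0.0334, the knockdowns with 0.161, 0.0776 and 0.0414, and only libraries numbered 1 correlated best with their own number. With the block, 0, 0 and 0 lists passed an estimated correlation, and 6, 11 and 3 passed fry.

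With 1 library left out, the counts ran from 868 to 1839 (DNMT3a siRNA), 287 to 1781 (DNMT3b siRNA) and 524 to 1962 (between them), and shared calls from 190 to 723. With DNMT3b siRNA, log2 fold changes ran from -1.69 to -1.13 for Dnmt3b, from -0.0973 to 0.0781 for Dnmt1, from -0.184 to 0.0200 for Vcam1 and from -0.0298 to 0.0767 for Gata4, of which the last 3 never passed. The cause was not tested.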

Other observations

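After DNMT3b siRNA, 145 genes fell against both other groups and had a 3' UTR to search. The word GCATGTA stood in 35 of them (24.1%) against 8.01% of other genes (adjusted p = 1.76e-05, stratified z test), and 6.79% of the genes with the word fell against 2.13% of those without. With DNMT3a siRNA these shares were 8.06% and 5.88%. GCATGTA was picked for standing out in these same fallen genes, so its shares with DNMT3b siRNA add no support beyond the test over all words. In the 145 fallen genes 3 words passed, with GGGAGCG (adjusted p = 0.00120) and GGTCAAG (adjusted p = 0.00736, stratified z test) besides GCATGTA. GCATGTA and GGTCAAG occur in Dnmt3b transcripts, while GGGAGCG does not. For the word GCCAATA of the DNMT3a comparison, its reverse complement, examined after the result was seen, had a stratified z of only 0.562, against 20.5 for the word itself. Prkcb, which fell with DNMT3a siRNA, held GCATGTA.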
